A study of Acromyrmex echinatior with 18 samples.

How the data were processed

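RNA was sequenced from pooled heads and DNA from bodies of gynes, large workers and small workers of 3 colonies (Ae322, Ae356 and Ae363, written as replicates A, B and C), with 1 RNA and 1 DNA library per caste and colony. Per the labels' protocols the RNA libraries were strand-specific and made from polyadenylated RNA, and reads were paired and 90 bases long. The submitters' processing notes name BWA 0.5.9-r16. The rules by which editing sites were chosen are not given in the sources used here. The authors deposited a table of 17229 sites with, per the file headers, the counts of reads with the reference base and with the edited base in the DNA and the RNA of each sample, a mark where the authors called the site in that sample, the scaffold and position in assembly Aech_2.0, the annotated element, the gene and the name of its fly ortholog. In all 9 DNA libraries every site had at least 10 reads and 0 reads with the edited base, so the table holds only sites selected that way, and levels at sites near the detection limit depend on this selection.

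The editing level was the number of edited reads divided by all reads of a site in a library. Tests used the 5720 sites with at least 10 RNA reads in all 9 libraries, with a median of 56.4 reads per site and library. Each site was tested with a quasi-binomial logistic model in R 4.3.3, with the Pearson dispersion moderated across sites by squeezeVar of limma 3.58.1 and kept at 1 or above, F tests and Benjamini-Hochberg adjustment at 0.05. squeezeVar with its default options gave an infinite prior, and with it 1 dispersion of 1.88 for all sites. Before the report was written, 4 settings of squeezeVar (default, trend on depth, robust, both) were each run with and without the colony as a block and their counts of calls were seen. The default without block stayed the main test because it had been fixed before the data were examined, and all counts are given in the closing section. On simulated data for the 3 castes (5720 sites, 200 of them changed), the test recovered 22% of sites changed by a log odds of 1 and 77% of those changed by 2, with 7.48% false calls. For gynes against small workers it recovered 18% and 74%, with 7.07% false calls. In the simulation all sites shared 1 setting for the spread between libraries, without a colony effect or an overall shift between castes. Its share of false calls therefore does not cover sites with a larger spread of their own.

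Replicate letters mark the colony, so they pair the samples. Deviations from the caste means correlated between libraries of the same colony with r from -0.00696 to 0.0512 (median 0.0257), and between libraries of different colonies with r from -0.0394 to 0.0319 (median -0.00669). The blocked fit leaves 4 residual degrees of freedom, and squeezeVar then gave a prior of 1.3 degrees of freedom. Replicate libraries of 1 caste differed by more than sampling noise in all 9 pairs (chi-square per degree of freedom 1.73 to 2.08), so all 9 libraries were counted separately.

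Mean levels per library were compared with exact two-sided permutation tests. Genes were tested with limma's moderated F test on the arcsine-square-root of the mean level over their tested sites. The 22 sites that lie in 2 genes were left out of gene-level tests. Gene lists were matched by word patterns to the protein and fly ortholog names and tested with camera at a preset correlation of 0.01 and with an estimated one, where at least 5 genes had been tested. The patterns of the cytoskeleton list also match other words (actin in interacting, formin in forming), so a version with actin as a whole word was added. Shares of called sites by region were compared with Fisher's exact test. Sites were named by a rule fixed beforehand: among called sites in genes whose 3 levels in each caste do not overlap, the 8 largest differences in each direction, at most 1 per gene, together with the 10 genes with the most sites and up to 3 genes per list with the smallest p.

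Alternatives were coverage minimums of 5 and 20 reads, limma on arcsine-square-root levels, the replicate block, no floor on the dispersion, A-to-G changes alone, sites with a mean level of at least 5%, other summaries per library or gene, and leaving out each library. Another count-based test planned as an alternative was not run. It was kept for files whose cells hold plain counts, and the packed cells themselves did not prevent it. Amino acid changes and sequence around sites were not analysed here, as no genome sequence was used. Tables and plots were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Reads carry no molecular identifiers, so read depth bounds counting error only. Heads were pooled, so the spread between libraries of a caste is that between colonies' pools and not between ants. The reported site tests took this spread as 1 dispersion shared by all sites and not as each site's own. Fisher's exact tests count sites and measure no spread between pools.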

Results

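RNA editing, the change of single bases in RNA after transcription, was measured in heads of the leaf-cutting ant Acromyrmex echinatior. In animals its most frequent kind turns adenosine into inosine, which sequencing reads as G, and is carried out by ADAR enzymes. Gynes (females that can become queens), large workers and small workers were each sampled from 3 colonies, written here as A, B and C, which gave 9 RNA libraries and 9 matched DNA libraries. Each gyne and large worker RNA library came from 50 pooled heads and each small worker library from 200. The table held 17229 sites on 405 scaffolds of the genome, with the reads of each base in every library. RNA reads over these sites numbered from 479998 in large workers of colony B to 1037408 in small workers of colony B, and all 3 small worker libraries were deeper than the other 6. The median site had between 8 and 22 RNA reads per library. Every site had at least 10 DNA reads in every library and 0 DNA reads with the edited base, a property of the sites that were kept for the table.

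A-to-G changes made up 16277 of the 17229 sites (94.47%). The next most frequent kinds were G-to-A with 451 sites, C-to-T with 189 and T-to-C with 167. Of all sites, 6999 lay in 1433 annotated genes. The 3' UTR held 3182 sites, introns held 3155, the 5' UTR held 358 and coding sequence held 304. A further 3276 sites lay in transposable elements outside genes and 6954 had no annotation. Among coding sites 41.78% were A-to-G, against 95.66% in the 3' UTR and 96.8% in introns. The genes with the most sites were led by Mdh1 (Aech_13462), a malate dehydrogenase, with 87 sites in its 3' UTR between positions 184398 and 186888 of scaffold 31. Aech_15068, an uncharacterized protein, had 74, the glycogen synthase gene CG6904 (Aech_14572) had 70, all in introns, and the metalloproteinase gene mmd (Aech_17011) had 64, also intronic. The chaperone gene Hsc70-4 (Aech_00116) had 58, the secretion activator Caps (Aech_02927) had 53 and the glutamine synthetase Gs1 (Aech_14517) had 48. Aech_03292 and Aech_07791, both uncharacterized, had 46 each and Tap42 (Aech_09719), a phosphatase regulator, had 45. All sites of these 10 genes were A-to-G.

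The first question was whether the castes differed in how much they edit. Over the 5720 sites with at least 10 RNA reads in all 9 libraries, the mean editing level was 11.8% ± 0.232 in gynes, 13.6% ± 0.558 in large workers and 15.8% ± 0.181 in small workers (SD, n = 3 each). In all 3 colonies the level was lowest in gynes and highest in small workers. Small workers lay 3.998 percentage points above gynes, large workers 1.88 above gynes and small workers 2.12 above large workers. Each of these differences had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. Both worker castes together lay 2.94 points above gynes (exact permutation p = 0.0238, n = 6 and 3, where the smallest possible p is 0.0119). The other split with as large a difference set the small worker libraries apart. This p therefore does not separate gynes against workers from small workers against the rest. With the replicate block, which compares castes within colonies, the same differences had an exact sign-flip p of 0.25, the smallest that 3 colonies allow. Over sites the authors called in all 9 libraries, a set chosen after seeing the data, the differences were larger, with small workers 6.25 and large workers 3.37 points above gynes and both worker castes together 4.8. An exact Friedman test of the 3 castes within colonies, added after the levels were seen, gave p = 0.0278. The same order of castes in all 3 colonies fixes that value, so the test only restates the order. From large to small workers the rise was seen at A-to-G sites and not at sites of the other changes. Over the latter, the level was 2.76% ± 0.227 in gynes, 3.21% ± 0.117 in large workers and 2.89% ± 0.135 in small workers (SD, n = 3 each), so that small workers lay below large workers there. From gynes to large workers both kinds rose, A-to-G sites by 2.05 points (15.97% of their gyne level) and the other changes by 0.452 points (16.37% of theirs, exact permutation p = 0.1, n = 3 each).

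**Figure D1:**
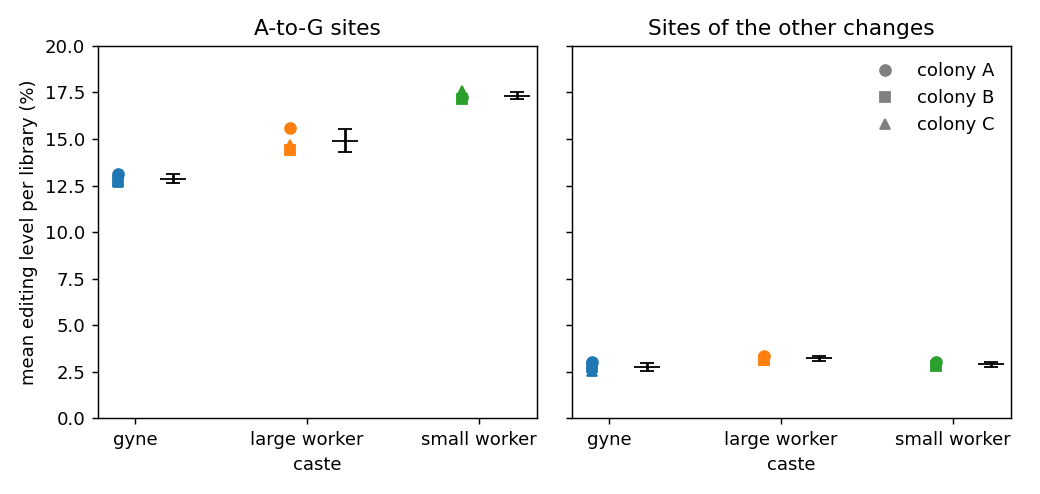
Mean editing level per library in percent (vertical axis) by caste (horizontal axis), for A-to-G sites on the left and for all other changes on the right, over sites with at least 10 RNA reads in all 9 libraries. Coloured symbols are libraries, with the shape giving the colony, and black marks are the mean and SD of 3 libraries. On the left all 3 small worker libraries lie above all others, and on the right the castes lie between 2.76% and 3.21%.

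The second question was which sites differed among the 3 castes. Of the 5720 sites, 365 in 85 annotated genes or gene pairs passed an adjusted p of 0.05 in the quasi-binomial test, and 1171 had an unadjusted p under 0.05. Sites in the 3' UTR were called more often than other sites, 8.5% against 5.43% (odds ratio 1.62, adjusted Fisher's exact p = 0.000129), while sites without annotation were called less often, 5.01% against 7.24% (odds ratio 0.676, adjusted p = 0.00289). The shares in coding sequence (7 of 202 sites), introns (42 of 665), the 5' UTR (2 of 74) and transposable elements outside genes (53 of 806) did not pass this test, nor did that of all sites inside transposable elements (113 of 1528). Sites are not independent, so these p-values describe these sites. The test also did not hold read depth equal between regions. The coverage minimum kept 1777 of 3182 sites in the 3' UTR, 665 of 3155 in introns and 2196 of 6954 without annotation. Deeper sites were called more often, 390 of 8326 with a minimum of 5 reads and 324 of 3370 with 20. Whether depth accounts for the difference between regions was not tested. In the 3' UTR the mean level was 11.7% ± 0.232 in gynes, 13.7% ± 0.564 in large workers and 16.2% ± 0.11 in small workers, and in coding sequence it was 4.89% ± 0.595, 5.53% ± 0.389 and 6.03% ± 0.061 (SD, n = 3). These levels are over all kinds of change. A-to-G made up 95.66% of the table's sites in the 3' UTR but 41.78% in coding sequence, so the 2 regions cannot be compared directly. The count of 365 depended on the overall shift between castes and on the model of the spread between libraries. Relative to the overall shift of each caste 64 sites passed, of which 48 were among the 365. That test gave every site 1 shared dispersion of 1.88, although the site's own dispersion reached 86.1. In a fit with the replicate block 0 sites passed (833 at an unadjusted p under 0.05), limma on arcsine-square-root levels gave 0 (785 unadjusted), and leaving out 1 library at a time gave between 0 (without small workers of colony A) and 61.

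Gynes and small workers differed at the most sites. Editing was higher in small workers at 463 of the 471 called sites and lower at 8, with a median difference of 13.3 percentage points. In the 3' UTR of sqd (Aech_00895), an RNA-binding protein, the site at position 688856 of scaffold 99 was edited at 33.9% ± 9.03 in gynes and 79.5% ± 17.2 in small workers (SD, n = 3, adjusted p = 7.54e-07, 27 to 80 reads per library). In the 3' UTR of CG11665 (Aech_14367), a monocarboxylate transporter, position 82764 of scaffold 544 went from 10.5% ± 3.46 to 46.7% ± 4.44 (adjusted p = 2.44e-08). An intronic site of the GABA receptor gene Rdl (Aech_17865), at position 340447 of scaffold 465, was at 23.6% ± 6.27 in gynes and 57.6% ± 5.73 in small workers (adjusted p = 0.0195). The other sites with the largest rises, at most 1 per gene, lay in the 3' UTR of CG15738 (29.5% to 72.0%), in introns of the RNA helicase gene CG3225 (6.99% to 47.0%) and of Aech_16122 (42.8% to 77.6%), in the 3' UTR of S6k, a growth-control kinase (20.1% to 54.3%), and in that of Pep, a zinc finger protein (39.9% to 73.9%). The 3 levels of gynes and of small workers did not overlap at 426 of the 471 sites. Over all 5720 sites that was so at 23.6%, where chance gives 10%. Among the called sites in genes whose levels did not overlap, 2 were lower in small workers. One lay in an intron of Aech_12009, at 22.1% ± 2.61 in gynes and 0% in all 3 small worker libraries, and the other in an intron of Aech_03054, a pheromone-binding protein, at 3.35% ± 1.82 and 1.21% ± 0.836. Blocking by colony, with the replicate block, left 0 sites (1071 at an unadjusted p under 0.05), limma on arcsine-square-root levels gave 0 (922 unadjusted), and without 1 library the count lay between 52 (without small workers of colony C) and 219. The site's own dispersion exceeded the shared 1.88 at 211 of the 471 called sites, among them those of sqd (3.89), CG15738 (2.27) and Aech_03054 (6.12), whose adjusted p rests on a spread smaller than their own. Some sites exceed a shared value by chance alone, and that share was not computed for this count or for those of the other comparisons. Relative to the overall shift of each caste, 72 sites passed, 44 higher and 28 lower in small workers.

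**Figure D2:**
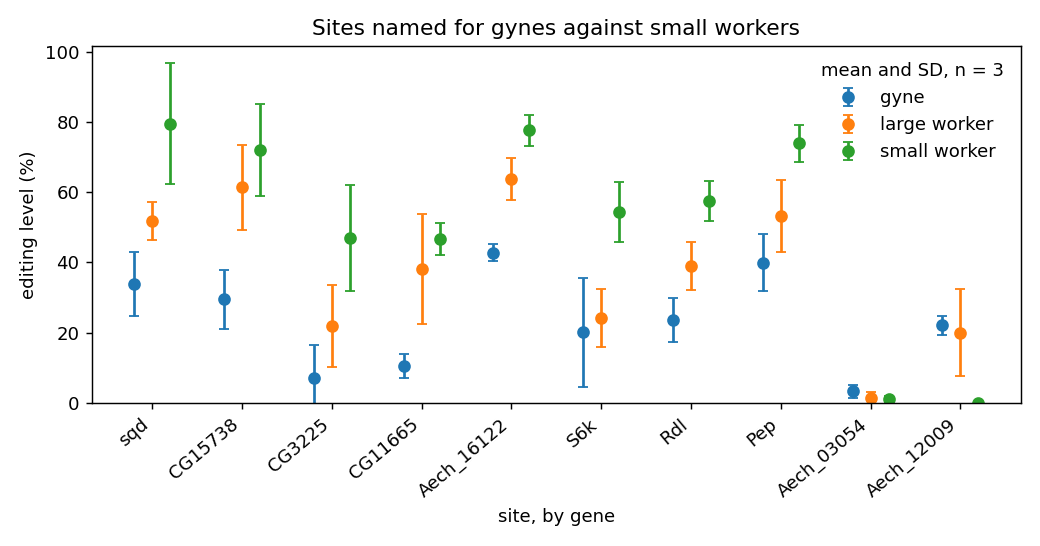
Editing level in percent (vertical axis) at the 10 sites named for gynes against small workers (horizontal axis, by gene). Points are means and bars are SDs of 3 libraries per caste, with bars cut at 0. The first 8 sites are higher in small workers, led by sqd at 33.9% and 79.5%, and the last 2 are lower.

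Gynes and large workers differed at 27 sites in 8 annotated genes, 25 higher and 2 lower in large workers, with a median difference of 10.3 percentage points. The CG11665 site was at 38.1% ± 15.6 in large workers against 10.5% ± 3.46 in gynes (SD, n = 3, adjusted p = 0.00103). Sites in the 3' UTR of VhaSFD, a subunit of the proton pump, went from 30.3% ± 5.85 to 45.0% ± 1.79, of the splicing factor gene pUf68 from 37.1% ± 1.46 to 48.1% ± 2.34 and of CG5515 from 5.38% ± 3.81 to 16.2% ± 0.519. An intronic site of Mapmodulin went from 36.1% ± 2.72 to 46.4% ± 2.14, and a 3' UTR site of Hsc70-4 from 22.1% ± 1.2 to 30.2% ± 2.66. A coding G-to-A site of sls (titin, a muscle protein), covered by 9964 to 18378 reads, was at 3.44% ± 0.743 in gynes and 5.08% ± 0.614 in large workers. The site's own dispersion exceeded the shared 1.88 at 18 of the 27 called sites, among them those of sls (13.2), pUf68 (4.15), Hsc70-4 (2.79) and VhaSFD (2.24), whose adjusted p (1.31e-12 for sls) rests on a spread smaller than their own. The replicate block left 0 sites (485 at an unadjusted p under 0.05), limma on arcsine-square-root levels gave 0 (514 unadjusted), and without 1 library the count lay between 0 and 2, the lowest without any 1 of the large worker libraries or small workers of colony A or B. A dispersion that followed depth left 7 sites, and relative to the overall shift of each caste 5 passed, 3 higher and 2 lower.

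Large and small workers differed at 50 sites in 16 annotated genes or gene pairs, 49 higher and 1 lower in small workers, with a median difference of 11.1 percentage points. Among the 27 called sites in genes whose levels did not overlap, the largest rise lay in the 3' UTR of Tap42, from 15.4% ± 5.77 in large workers to 47.5% ± 7.29 in small workers (SD, n = 3, adjusted p = 0.0327). A 3' UTR site of Cdk9, a kinase of transcription elongation, went from 36.3% ± 9.25 to 66.7% ± 5.45, and the sqd site from 51.8% ± 5.31 to 79.5% ± 17.2. Further rises lay in the 3' UTR of ATPsyn-gamma, a subunit of the ATP synthase (16.6% to 38.0%), of CG5515 (15.2% to 35.4%) and of nuf (4.58% to 17.0%), in an intron of Dsp1 (24.0% to 43.6%) and in an intronic site shared by Aech_10515 and Aech_10516 (28.1% to 58.8%). At the Tap42, Cdk9, nuf and shared sites the mean of gynes lay above that of large workers. The only called site that was lower in small workers was the sls site. Under the replicate block 0 sites passed (575 at an unadjusted p under 0.05), limma on arcsine-square-root levels gave 0 (517 unadjusted), and leaving out any 1 of the 9 libraries gave 0. Relative to the overall shift 9 sites passed, 5 higher and 4 lower, and at 32 of the 50 sites, those of sqd, nuf and sls included, the site's own dispersion exceeded the shared one.

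Gynes differed from the mean of both worker castes at 236 sites in 65 annotated genes or gene pairs, 226 higher and 10 lower in workers, with a median difference of 11.5 percentage points. The fit with the replicate block gave 0 sites (778 at an unadjusted p under 0.05), limma on arcsine-square-root levels gave 0 (789 unadjusted), and without 1 library the count lay between 1 (without large workers or without small workers of colony A) and 53. Relative to the overall shift 24 sites passed, 12 higher and 12 lower.

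With the gene as the unit, limma's moderated F test on the mean level over a gene's tested sites called 8 of 700 genes among the 3 castes, all at an adjusted p of 0.0439. In 7 of them small workers had the highest mean. Alas, an enzyme of heme synthesis, was at 2.07% ± 1.21 in gynes, 6.42% ± 0.936 in large workers and 15.2% ± 2.15 in small workers (SD, n = 3). The peroxidase gene Pxd was at 4.05% ± 2.14, 8.64% ± 0.901 and 17.9% ± 2.01, and ATPsyn-gamma at 4.46% ± 0.834, 6.88% ± 1.77 and 17.1% ± 2.77. CG5515, with 14 tested sites, was at 4.02% ± 0.866, 7.44% ± 1.45 and 14.8% ± 1.25. Aech_12053, Ip259 and Aech_16122 were also highest in small workers. CG6432, an acyl-CoA synthetase with 1 tested site, a G-to-A change, went the other way, from 11.8% ± 4.89 in gynes to 1.5% ± 1.36 in large workers and 0% in small workers. The contrast of gynes with small workers called 16 genes, 15 higher and 1 lower in small workers, where 71.4% of all 700 genes had a higher level in small workers. Gynes against both worker castes called 4 genes, 3 higher and 1 lower in workers (117 at an unadjusted p under 0.05), where 75.6% of all genes were higher. The contrasts of gynes with large workers and of large with small workers called 0 by limma (61 and 82 at an unadjusted p under 0.05). With the replicate block 0 genes passed among the 3 castes by limma (101 at an unadjusted p under 0.05, against 119 without the block), 0 passed with a coverage minimum of 5 reads, 4 with 20 and 3 with levels of summed reads, among the 230 genes with at least 3 tested sites 65 passed, and without 1 library the count lay between 0 and 14 (without large workers of colony A). Relative to the mean over genes of each library, a setting chosen after seeing the data, limma called 0 genes among the castes (63 at an unadjusted p under 0.05), and of the 16 and the 4 genes only CG6432 passed.

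Of the 13 gene lists fixed before the data were examined, 9 had enough tested genes for camera and 4 did not. Camera on the 9 lists and 3 pairwise contrasts gave 0 of 27 tests past the threshold, with a smallest adjusted p of 0.714, and 0 with an estimated correlation (smallest adjusted p = 0.771). The smallest unadjusted p was 0.0595. Within the lists, gene-level calls between gynes and small workers were few, and none of them passed relative to the mean over genes of each library. Of 49 kinase and phosphatase genes 1 was called as higher in small workers, Argk, an enzyme of the energy reserve, at 1.21% ± 0.279 and 6.59% ± 0.869 (SD, n = 3, limma adjusted p = 0.0491), and 0 were called when adjusted over the list alone (1 between large and small workers). In this list the smallest p among the castes belonged to Aech_14823 (BUB1), at 6.98% in large workers and 38.6% in small workers, followed by Argk and Aech_09454. Of 27 transcription factor genes 1 was called, CG31365, a zinc finger protein, at 61.2% ± 8.43 and 85.8% ± 2.86 (adjusted p = 0.0361), and 3 when adjusted over the list alone. Aech_17755 and Pep (17.3% in gynes and 26.6% in small workers) came next. Aech_17755 is named for ankyrin repeats and a zinc finger domain, and its name matched both this list and the cytoskeleton list. Of 30 cytoskeleton and motor genes 1 was called, and 5 when adjusted over the list alone. The called gene was skap, a mitochondrial enzyme of the citric acid cycle and no cytoskeleton protein, which entered the list because the pattern formin also matches the word forming in its name, at 4.4% ± 0.389 and 12.4% ± 1.96 (adjusted p = 0.0491). Nuf (5.57% and 13.3%) and Aech_17755 followed. With actin taken as a whole word, that list held 19 tested genes, nuf not among them, and the 1 called was again skap. Adjusted over this shorter list alone, 2 were called instead of 5.

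Of 26 genes of RNA binding and processing 0 were called by limma over all genes or over the list alone. The 3 with the smallest p were sqd (11.6% in gynes and 24.2% in small workers), the splicing factor gene Aech_14890 (9.27% and 18.2%) and Aech_08501 (15.9% and 25.7%). Of 13 ubiquitin pathway genes 0 were called over all genes and 4 when adjusted over the list alone (1 between gynes and large workers), and Aech_02281 (13.3% and 27.0%), Aech_10516 (6.2% and 13.4%) and Aech_07753 (7.06% and 15.9%) had the smallest p. Of 9 synaptic vesicle genes 0 were called, with Aech_13649, a synaptotagmin, at 17.8% and 26.6%, Aech_10285, a synaptobrevin, at 9.0% and 13.2%, and Aech_17864 at 0% in both. Of 5 neurotransmitter receptor genes 0 were called, with Rdl (Aech_17865) at 13.5% and 25.4%, Aech_08297 at 0% and 2.68% and Aech_16950 at 11.8% and 10.5%. The 5 include Aech_05275, named as a glutamate receptor-interacting protein and not as a receptor, with 17 of the list's 37 tested sites. It is also among the 22 neuronal-list genes used below. Of 7 small GTPase regulators 0 were called, with Aech_11669 at 5.65% and 7.63%, Aech_12648 at 3.59% and 0.388% and Aech_02951 at 3.35% and 5.87%. Of 5 fat body and gland genes 0 were called, with Aech_03703 (yellow) at 7.24% and 15.4%, Aech_00204, a cytochrome P450, at 8.29% and 15.97%, and Aech_08355 at 2.54% and 0%. The lists of voltage-gated ion channels (4 tested genes), cell adhesion and axon guidance (4), muscle (3) and eye and antenna (4) were too small for camera and had 0 calls by limma over all genes. Adjusted over the list alone, 1 gene of the channel list was called between gynes and small workers and 0 in the other 3 lists. The called gene was Aech_17834, named as a TWiK family potassium channel and not as a voltage-gated one. The potassium channel genes Aech_17834 (2.24% and 6.17%), Aech_06394 (26.38% and 26.37%) and Aech_10060 (3.81% and 3.65%) had the smallest p of the channels. For adhesion they were Aech_02795, a cadherin (2.75% and 4.1%), Aech_07318, a teneurin (5.51% and 7.96%), and Aech_09520 (11.4% and 9.29%). The muscle genes Aech_07607, titin (2.51% and 2.91%), Aech_15785, troponin C (5.76% and 8.13%), and Aech_17649, myosin (10.1% and 13.4%), and the sensory genes Aech_02024, an arrestin (1.33% and 6.33%), Aech_03054 (3.35% and 1.21%) and Aech_00485 (7.9% and 11.9%) had the smallest p of their lists.

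The last comparison asked how far editing followed the colony. With caste in the model, 0 of 5720 sites differed among the 3 colonies in the quasi-binomial test (5.63% of sites at an unadjusted p under 0.05), and limma on arcsine-square-root levels gave 0 (6.14%). In the same 2 models the caste term also gave 0 calls, but 14.6% and 12.8% of sites had an unadjusted p under 0.05. On the arcsine-square-root scale caste accounted for 33.3% of the variation between libraries and colony for 23.3%, where 25% falls to either by chance. Without the floor on the dispersion, 298 sites were called for the colony. That setting lets a site take a dispersion under 1, moderated by a prior of only 1.3 degrees of freedom, so these calls depend on the floor. No count without the floor is given for the caste term of this model.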

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

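The block, limma, coverage and left-out libraries were chosen before the data were examined. The block together with limma, the overall shift, the options of the dispersion, the sites called in all 9 or all 3 gyne libraries, the split by kind of change, the centring of gene levels and limma for colonies were chosen after seeing the data. Counts of sites are given in the order 3 castes, gynes against large workers, gynes against small workers, large against small workers, gynes against both worker castes. The reported counts were 365, 27, 471, 50 and 236. With the replicate block they were 0, 0, 0, 0 and 0, with limma on arcsine-square-root levels 0, 0, 0, 0 and 0, and with both 0, 0, 0, 0 and 0. Under the block with a dispersion that followed depth they were 0, 0, 0, 0 and 0, with a robust one 0, 0, 18, 0 and 0, and with both 0, 0, 0, 0 and 0. Without the block these 3 options gave 336, 7, 459, 35 and 205, then 378, 24, 493, 50 and 242, then 343, 10, 471, 48 and 211. All 8 fits of these options that were run are listed here. Relative to the overall shift of each caste the counts were 64, 5, 72, 9 and 24. Leaving out 1 library gave 0 to 61, 0 to 2, 52 to 219, 0 to 0 and 1 to 53. In those fits the prior had 3.48 to 10.84 degrees of freedom, where the reported fit had an infinite one. For gynes against large workers, leaving out a small worker library removed no compared reads and changed only the dispersion and its prior. The 27 calls then fell to 0, 0 and 1 (without small workers of colony A, B and C). For large against small workers the 50 calls fell to 0 without any 1 gyne library. These counts therefore rest on the dispersion and prior of the reported fit. For gynes against small workers, leaving out a large worker library also removed no compared reads. The 471 calls then fell to 127, 219 and 199 (without large workers of colony A, B and C). The prior then had 4.09, 6.69 and 6.51 degrees of freedom, so many of the 471 calls also rest on the reported dispersion and prior. For the 3 castes and for gynes against both worker castes the cause was not tested further. Coverage minimums, the floor, A-to-G changes alone, a level of at least 5% and sites called in all 9 or all 3 gyne libraries kept every site count within 1.5 times. Removing the floor of 1 could not change a fit whose shared dispersion was 1.88. The coverage minimums, A-to-G changes alone and the level of at least 5% also had an infinite prior, so they do not probe it.

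The mean level kept its direction in each comparison under every setting run on all changes or on A-to-G changes, but over sites called in all 9 libraries it rose from 3.998 to 6.25 (small workers against gynes), 1.88 to 3.37 (large workers against gynes) and 2.94 to 4.8 (workers against gynes). Over the other changes alone, small workers lay -0.321 percentage points from large workers and workers 0.292 above gynes (exact permutation p = 0.107). With the replicate block the workers' difference of 2.94 had a p of 0.25, the smallest 3 colonies allow. Genes called among the castes were 8, against 0 with a coverage minimum of 5, 4 with 20, 0 with the replicate block, 3 with summed reads, 0 relative to the mean over genes of each library, 65 among genes with at least 3 tested sites, where fewer genes were tested, and 0 to 14 without 1 library. The cause was not tested. Gene lists stayed at 0 calls under all settings run. Colony calls were 0, against 1 with a coverage minimum of 20 and 298 without the floor. Of the site classes, the 3' UTR and unannotated sites passed with coverage minimums of 5, 10 and 20. The edgeR alternatives were not run.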

Other observations

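Edited sites sat close together. Of the 16277 A-to-G sites, 13182 (81.0%) had another A-to-G site on the same strand within 50 bases, against 91 of 952 sites (9.56%) of the other changes. The share depends on how many sites are counted, so these shares cannot be compared directly. In 100 random draws of 952 A-to-G sites the share was 16.9% in the median (12.3% to 20.9%), above that of the other changes in each draw. Such draws also remove neighbours from real clusters, so they do not show how much of the gap follows from the number of sites. Sites that the authors called in all 3 libraries of a caste numbered 4798 in gynes, 5193 in large workers and 9302 in small workers, whose libraries were the deepest. Called in all 3 libraries of 1 caste and in no other library were 12 sites in gynes, 13 in large workers and 169 in small workers, of which 3, 3 and 41 had at least 10 reads in all 9 libraries. Adar (Aech_00367), the gene of the editing enzyme, was itself edited. Its 5 tested sites lay in the 5' UTR on scaffold 326, and the 1 at position 702714 was at 71.3% ± 17.4 in gynes, 69.5% ± 8.44 in large workers and 58.8% ± 10.7 in small workers (SD, n = 3), with no difference among castes past the threshold.

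The pattern followed up was the rise of the editing level from gynes through large to small workers. The tests below were written down after the mean levels, but before the values that decide them, had been seen, except the test of the step from gynes to large workers, which was chosen after its values were seen. By an error the test of nervous tissue had first been run on the genes of 1 of its 4 lists, where it argued against that explanation, and that outcome was known when it was run on all 4. Small worker libraries were deeper, so sites could have entered the table through them. Over sites called in all 3 gyne libraries the rise from gynes to small workers was 5.21 percentage points (SE 0.131 over colonies), which argues against that as the whole cause. A base mismatch that differs between libraries would raise the other changes too. From gynes to small workers they rose by 0.0293 of the A-to-G rise in points, and by 0.136 of it relative to the gyne levels. Both values argue against a mismatch for that difference. For the step from gynes to large workers a mismatch stays open. There the other changes rose by 0.22 of the A-to-G rise in points, but relative to the gyne levels by 1.02 times as much.

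A larger share of nervous tissue in small worker heads stays open. The 22 tested genes of the 4 neuronal lists changed by a median of 0.382 points between gynes and small workers, against 1.89 for the other 678 genes, a ratio of 0.202, and reads over sites of neuronal-list genes took a larger share in small workers in all 3 colonies (mean difference 0.409 points, SE 0.0401). Their mean change was 1.63 points (SE 0.711 over genes) against 2.78 (SE 0.183), and camera did not call the lists it tested. More Adar transcript is a candidate explanation as well. Reads over the Adar sites, as a share of reads over all sites, were higher in small workers than in gynes in 3 of 3 colonies (by 438, 547 and 376 reads per 1e+06), but in colony B large workers, at 265, lay below gynes, at 284, although their editing level was higher. Both measures come from reads at edited sites alone and are no measure of expression over whole genes, and a biological difference between castes stays open and untested. Small worker libraries alone were made from 200 heads, while gynes and large workers, which also differed in level, both had 50.

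Other splits of the libraries were counted for each comparison. For the 3 castes, 1 of 100 splits drawn from the 280 possible, the real one, gave as many sites (365, highest other 251). As many genes came from 1 of 100 (8, highest other 3). Both shares lie under 0.05, so chance is an unlikely source of either count as the unblocked tests give them. These splits ignore the pairing by colony, so they do not exclude chance. All 36 splits with 1 library of each colony in each group were also counted, a check chosen after the first counts were seen. The real split alone gave as many, 1 of 36 or 2.78%, the smallest share that 36 splits allow. The highest other counts were 227 sites and 1 gene. The blocked tests call 0 sites and 0 genes, so this says nothing of them. For gynes against workers, fitted with 2 groups, 2 of 84 splits gave as many sites as the real 199. The other, with 276, set the 3 small worker libraries apart, so that split follows a caste as well. The pairwise comparisons have only 10 splits each, too few for a share under 0.05, and the real split gave the most in each, being 1 of 10: 27 sites against at most 15 for gynes and large workers, 471 against at most 1 for gynes and small workers, and 50 against at most 12 for large and small workers.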
